A study of Macaca mulatta with 28 samples.

How the data were processed

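Total RNA from a dissected block that contained the CeA was sequenced in 28 male rhesus macaques, 1 library per animal, as stranded libraries depleted of ribosomal RNA. Per the labels, the animals belong to 4 drinking categories and 4 cohorts, with 8 animals in cohort 4 (8.24 years old at induction), 7 in cohort 5 (5.63 years), 8 in cohort 7a (4.18 years) and 5 in cohort 7b (5.69 years). The authors name CASAVA, FastQC, STAR 2.3.0e and edgeR without giving their order. The genome build and the annotation are not given in the sources used here. The deposited gene table holds a signal per gene, the reads over its exons multiplied by 1 upper-quartile factor per library. The deposited exon table holds a score per exon, the same quantity rounded to whole numbers. Both are called normalized reads. Each table has 30 columns, of which the 28 described in the labels were used and 2 were not used here.

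Both statements on units were checked on the values. In every gene column, 100% of values lay within 0.02 reads of a whole multiple of the column's smallest step, so whole reads could be recovered. The 75th percentile of the columns ranged from 971 to 988. The sum of a gene's exons divided by the gene value had a median of 1.00 (5th to 95th percentile 0.996 to 1.00) over single gene values of at least 100. The gene table held 15521 genes, 287 of them at 0 in every library, and 156345 exons were listed in the other. Of the gene symbols, 14051 matched the reference list and 14440 matched it with synonyms. Coordinates and chromosome names are those of the exon table, which splits chromosome 2 into 2a and 2b.

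The libraries held 1910514 to 25928489 reads over gene exons (median 16444833), and 3 reads corresponded to 1.82 to 24.1 normalized reads. Across 91 pairs of libraries of the same category, the variance between libraries was 9.93 to 113 times that of counting alone over the genes as a whole, which includes differences between animals, cohorts and dissected blocks. The 10 genes with most reads took 3.09% to 3.72% of a library.

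Genes with a value of at least 10 in at least 5 libraries were tested (13022 genes), on log2(value + 1). limma 3.58.1 in R 4.3.3 with a mean-variance trend compared heavy with low drinkers with cohort as a term. A fit with the 4 categories and cohort gave VHD, HD and BD against LD. A fit with the category as a number from LD to VHD gave the trend, and an F test with category as a term compared cohorts. p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and all tests were two-sided. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads. Exons were tested in the same way (112706 exons). Relative exon use was tested with limma's diffSplice in 9817 genes with at least 3 tested exons (109212 exons), by the F test.

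Gene lists, 35 in number, cover CeA peptides and receptors, cell types, neighbouring tissue, synaptic, stress, immune, epigenetic and metabolic genes and RNA quality. Lists with at least 5 tested members (34) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. A marker score is the mean of a list's log2 values, each centred on its mean over the 28 libraries. Scores were compared by a permutation test within cohorts with 100000 resamples, adjusted over 12 lists. Correlations across animals have permutation p-values, adjusted over 4 relations.

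The samples, the tests, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took genes with a symbol and a mean of at least 50 normalized reads. For heavy vs low drinkers it took the 15 higher and 15 lower genes with the largest fold among those past the threshold, filled to 10 per direction by smallest p where fewer passed. For VHD, HD and BD against LD and the trend it took 5 and 5 in the same way, for cohorts the 10 genes and for exon usage the 5 genes with the smallest p. In each list it took up to 4 members with the smallest p, and every member past the threshold where there were 6 or fewer. CRH, PDYN, PENK, SST, NPY, CRHR1, FKBP5, NR3C1, GFAP, MBP and ALDH2 were given in every category whatever their p. Genes outside the rule are described as chosen after their values were seen. Some items that the rule takes are not reported here.

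The pipeline was tested on simulated data, negative binomial reads drawn gene by gene from the measured means, library sizes and dispersions, with fold changes of known size placed in random genes. Genes varied independently of each other in these data. For heavy vs low, limma called 85.1% of 2-fold changes with 12 false calls, edgeR 85.1% with 9 and DESeq2 89.6% with 18. For cohorts, limma made 6 false calls and DESeq2 31. For exon usage in 2000 simulated genes, the F test made 15 false calls, Simes tests 56 and the test with an own spread per exon 23. The alternatives were a pseudocount of 0.5 or 8, no filter or a filter of 50 in 14 libraries, median-ratio rescaling, quantile normalization, robust priors with array weights, edgeR, DESeq2, no cohort term, age in place of cohort, cohort as a random effect, leaving out cohort 5, cohort 7a alone, 3 marker scores as covariates, no category term for cohorts, Simes tests for exon usage, medians for marker scores and leaving out each library in turn. Added after the data were seen were leaving out the 3 shallowest libraries (BD, LD and HD replicate 1), 4 marker scores as covariates and an own spread per exon. Figures were drawn with matplotlib 3.10.9.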

Results

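RNA was sequenced from a block of tissue around the central nucleus of the amygdala (CeA), a brain nucleus that joins stress and reward signals, in 28 male rhesus macaques that drank ethanol by choice. After an induction of about 90 days on 4% (w/v) ethanol, each animal could drink for 22 hours a day during more than 12 months. The labels sort the animals by intake into 10 low drinkers (LD), 5 binge drinkers (BD), 7 heavy drinkers (HD) and 6 very heavy drinkers (VHD). BD animals took at least 2 g/kg on at least 55% of days and reached 80 mg/dl of blood ethanol every year. HD animals took at least 3 g/kg on at least 20% of days. VHD animals averaged over 3 g/kg a day and passed 4 g/kg on at least 10% of open access days, and LD animals met none of these definitions. No animal without ethanol was among the 28. HD and VHD animals (13, called heavy here) were compared with LD and BD animals (15, called low), with cohort as a term. The 4 cohorts were uneven. Cohort 5 held 7 heavy animals and no low animal, so heavy and low met in cohorts 4, 7a and 7b. VHD and LD met only in cohort 7a. With cohort as a term, cohort 5 adds to the estimate of spread but not to the heavy vs low folds. Means by group and counts of animals above or below a mean take no account of cohort.

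The libraries held 1910514 to 25928489 reads over gene exons, with a mean of 15651665 ± 5689386 (SD, n = 28). The mean was 15883142 reads in LD, 14315995 in BD, 17380051 in HD and 14362478 in VHD. BD replicate 1 (1910514 reads), LD replicate 1 (6474295) and HD replicate 1 (7412823), all from cohort 4, were the 3 shallowest libraries. Between 12903 and 14331 genes had reads in a library.

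**Figure D1:**
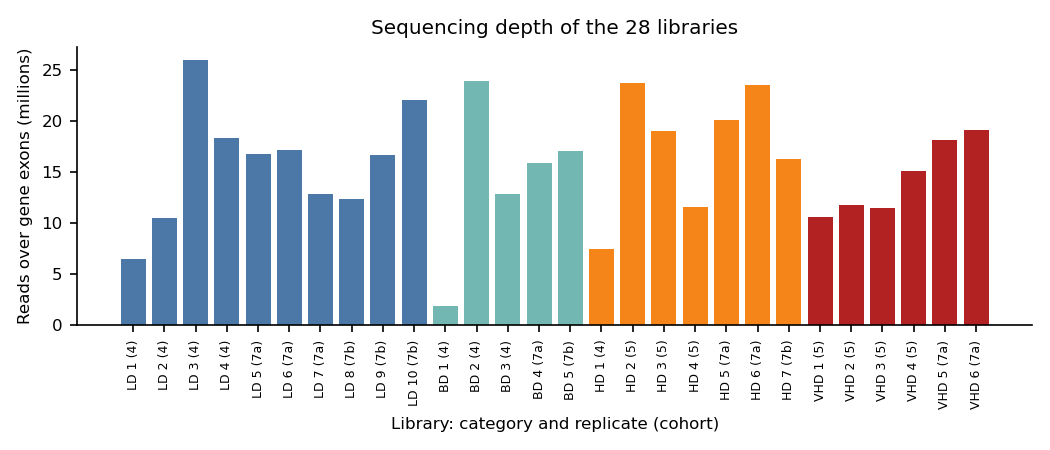
Bars give the reads over gene exons of each of the 28 libraries, coloured by drinking category, with the cohort in brackets after the replicate. BD replicate 1 had the fewest, 1910514, and LD replicate 3 the most, 25928489.

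In heavy drinkers, the mitochondrial ribosome gene MRPL13 was lower in 13 of 13 animals than the mean of the low drinkers, at 471 ± 43.5 against 561 ± 66.6 normalized reads (SD; n = 13 and 15), a fitted fold of 0.811 (95% interval 0.722 to 0.913). NDUFAF2, an assembly factor of mitochondrial complex I, was lower in 12 of 13, at 169 ± 26.5 against 216 ± 38.9 normalized reads and a fold of 0.744 (0.626 to 0.884). CDKAL1, a tRNA-modifying enzyme, was higher in 10 of 13, at 286 ± 31.6 against 257 ± 20.6 normalized reads and a fold of 1.23 (1.12 to 1.35). RORA, a nuclear receptor of the circadian clock, was higher in 11 of 13, at 2152 ± 304 against 1824 ± 251 normalized reads and a fold of 1.26 (1.09 to 1.46). None of these genes passed the test over all genes. The means and the counts out of 13 include the 7 heavy animals of cohort 5, which do not enter the fitted folds. The other higher genes with the smallest p were GLT25D2 (fold 1.36), ARFGEF1 (1.16), EOGT (1.25), WDR52 (1.67), ARHGAP21 (1.21), MPDZ (1.22), ZNF792 (1.41) and PDE4DIP (1.29). The other lower ones were THAP3 (fold 0.759), CD93 (0.665), TRAPPC4 (0.819), MCM2 (0.800), C17orf49 (0.812), TMEM91 (0.680), THAP4 (0.824) and RBM10 (0.857). WDR52 was above the low mean in 5 of 13 heavy animals, PDE4DIP above it in 6 of 13 and TMEM91 below it in 7 of 13. Within cohorts 4, 7a and 7b, the heavy minus low log2 difference was 0.41, 0.27 and 0.25 for CDKAL1, 0.40, 0.22 and 0.53 for RORA, −0.40, −0.31 and −0.19 for MRPL13, and −0.60, −0.42 and −0.26 for NDUFAF2. For PDE4DIP it was 0.52, 0.47 and −0.06, and for TMEM91 −0.51, −0.80 and 0.00, so neither difference was seen in cohort 7b. For WDR52 it was 1.46, 0.10 and 1.56. Cohort 4 and cohort 7b held 1 heavy animal each, so the WDR52 fold rested mainly on these single animals.

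By limma, 0 of 13022 genes had an adjusted p under 0.05 between heavy and low drinkers, and the lowest adjusted p was 0.998. At an unadjusted p under 0.05 there were 544 genes, 248 higher and 296 lower, where chance alone gives 651. This count depended on the model. It was 1480 with 3 and 1551 with 4 marker scores as covariates, and 1005 with robust priors and array weights, each with 0 genes past the threshold. The other settings gave 335 (age in place of cohort) to 829 (cohort 7a alone), and leaving out 1 library at a time gave 284 to 890. edgeR called 0 genes (585 at an unadjusted p under 0.05) and DESeq2 called 1 (629), SIRPB1, chosen after its values were seen. For 90.0% of the genes, the 95% interval of the fold lay within 2-fold in either direction, so larger differences are excluded for those genes singly. These p-values measure spread between animals. Folds are on the log2(value + 1) scale, which understates differences of genes with low values.

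Of 11 genes of the CeA and of ethanol biology fixed beforehand, the opioid precursor PENK had the largest ratio between its highest and lowest category mean. Its mean was 12044 ± 9682 normalized reads in LD (n = 10), 8449 ± 8732 in BD (n = 5), 11919 ± 9574 in HD (n = 7) and 3656 ± 3495 in VHD (n = 6). CRH, the stress peptide corticotropin-releasing hormone, had means of 57.7 ± 14.8, 48.0 ± 21.5, 72.1 ± 26.7 and 33.9 ± 10.4 normalized reads in the same order. GFAP, the astrocyte filament protein, had means of 35143 ± 9534, 36493 ± 13984, 33753 ± 16947 and 61445 ± 22137. MBP, a myelin protein, had means of 3807 ± 985, 4819 ± 1302, 4504 ± 1240 and 6154 ± 2388. FKBP5, a glucocorticoid-induced chaperone partner, had means of 262 ± 54.0, 288 ± 70.7, 279 ± 90.6 and 349 ± 93.9. Against low drinkers, heavy drinkers had a fold of 0.417 (0.167 to 1.04) for PENK, 1.06 (0.687 to 1.65) for CRH, 1.03 (0.671 to 1.58) for GFAP, 1.16 for MBP and 1.12 for FKBP5, none past the test. For PENK, the heavy minus low log2 difference was 0.33, −2.49 and 0.06 within cohorts 4, 7a and 7b, so its fold rested on cohort 7a. Each of the 11 genes differed in sign between these cohorts.

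The dynorphin precursor PDYN had means of 1179 ± 455, 1015 ± 332, 978 ± 303 and 941 ± 399 normalized reads in LD, BD, HD and VHD, and somatostatin (SST) of 2680 ± 888, 2054 ± 896, 3278 ± 1767 and 2375 ± 1131. Neuropeptide Y (NPY) had means of 1053 ± 417, 1174 ± 413, 922 ± 256 and 1192 ± 428. The CRH receptor CRHR1 had means of 151 ± 44.8, 155 ± 44.9, 139 ± 61.7 and 142 ± 38.8, and the glucocorticoid receptor NR3C1 of 2438 ± 174, 2568 ± 134, 2437 ± 188 and 2661 ± 283. ALDH2, which oxidizes acetaldehyde, had means of 3645 ± 426, 3545 ± 504, 3723 ± 603 and 3879 ± 329. The heavy vs low folds were 0.905 for PDYN, 0.841 for SST, 0.996 for NPY, 1.06 for CRHR1, 0.986 for NR3C1 and 0.998 for ALDH2, none past the test. Under at least 1 alternative setting, the heavy vs low sign turned for CRH, SST, NPY, CRHR1, FKBP5, NR3C1, GFAP and ALDH2.

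PENK followed the score of striatal medium spiny neuron genes across the 28 animals, with Pearson r = 0.770 and Spearman rho = 0.852. The permutation p was 1e-05 for each, the smallest that 100000 permutations can give, and 4e-05 for r after adjustment over the 4 relations computed. Without the 2 animals farthest from the median score, r was 0.789. It was 0.744 in cohort 4, 0.797 in cohort 5 and 0.830 in cohort 7a, while cohort 7b held 5 animals, too few for a value.

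**Figure D2:**
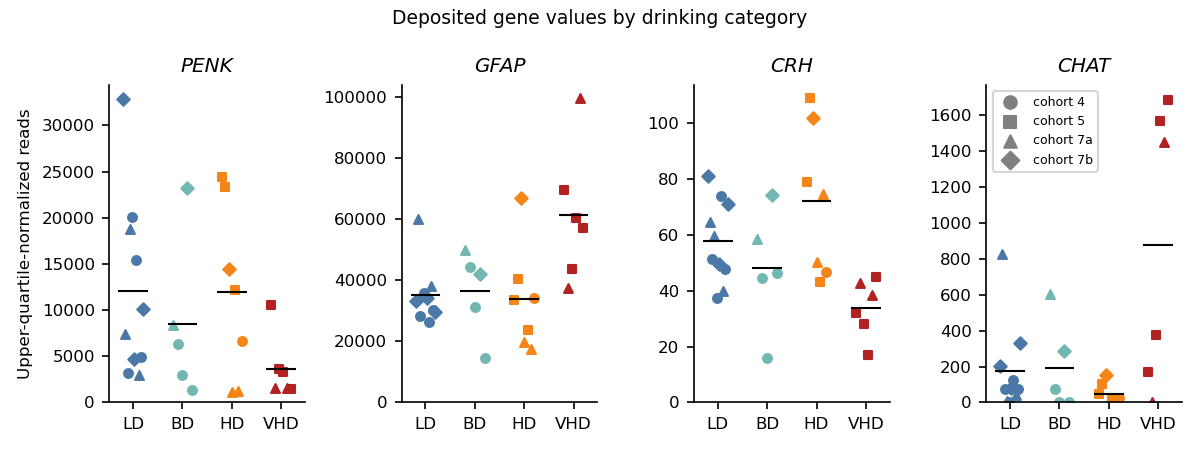
Each point is 1 animal, with its upper-quartile-normalized reads of PENK, GFAP, CRH or CHAT on a linear axis by drinking category; the shape gives the cohort and the line the category mean. VHD animals had a mean PENK of 3656, GFAP of 61445, CRH of 33.9 and CHAT of 875 normalized reads.

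Genes for the cytosolic ribosome lay slightly lower in heavy drinkers, with 31 of 31 members below 1-fold and a median log2 fold change of −0.12 (RPL11 0.845-fold, RPL30 0.848-fold, RPS9 0.840-fold). Nuclear genes of oxidative phosphorylation had 21 of 23 members lower and a median of −0.10 (NDUFV1 0.857-fold, COX4I1 0.882-fold). Circadian clock genes had 13 of 15 members higher and a median of 0.08, led by RORA (1.26-fold), PER1 (1.32-fold) and CLOCK (1.13-fold). GABAergic neuron genes had 9 of 12 members lower and a median of −0.18, led by the vesicular GABA transporter SLC32A1 (0.623-fold) and the GABA-synthesizing enzymes GAD2 (0.688-fold) and GAD1 (0.817-fold). By camera with a preset correlation, the adjusted p was 5.52e-08 for the ribosomal list, 0.000191 for oxidative phosphorylation, 0.0121 for the clock and 0.0463 for GABAergic neurons. For each of these 4 lists, camera gave an adjusted p = 0.677 with an estimated correlation, and fry an adjusted p of 0.795, so no list call held. Fold changes also followed transcript length. The median log2 fold change was −0.07 in the fifth of genes with the shortest exon length and 0.06 in the longest, and the Spearman correlation across genes, which are not independent replicates, was 0.296. Within cohorts 4, 7a and 7b the list medians were −0.28, −0.13 and 0.06 for ribosomal proteins, −0.42, −0.01 and −0.12 for oxidative phosphorylation, 0.00, 0.22 and 0.13 for the clock and 0.20, −0.28 and 0.11 for GABAergic neurons. The oxidative phosphorylation call ended without the 3 shallowest libraries (median −0.04), and also without HD replicate 1 alone.

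The remaining lists did not pass camera between heavy and low drinkers, and in all 34 tested lists 0 members passed over all genes and 0 adjusted over the list alone (limma; the lists held 0 to 3 members at an unadjusted p under 0.05). Among CeA lists, the median log2 fold change was −0.08 for neuropeptides (neurotensin gene NTS 0.431-fold) and −0.07 for receptors and identity genes (melanocortin receptor MC4R 0.505-fold). It was −0.12 for striatal medium spiny neurons, 0.43 for cortical and basolateral glutamatergic neurons, −0.01 for pan-neuronal genes, −1.03 for hypothalamic and basal forebrain genes and −0.20 for the globus pallidus, thalamus and habenula. For glia it was −0.03 for astrocytes, −0.09 for oligodendrocytes and myelin, 0.03 for oligodendrocyte precursors and −0.03 for microglia (AIF1 0.799-fold). Endothelial cells and pericytes had −0.02, and choroid plexus, ependyma and meninges −0.40 (water channel AQP1 0.567-fold). The blood list had 0 tested members of 12. Among synaptic lists, GABA-A receptor subunits had 0.00, glutamate receptors 0.02, presynaptic vesicle release 0.07, the postsynaptic density 0.02 and ethanol-linked potassium and calcium channels 0.13. The opioid and endocannabinoid system had −0.03, monoamine receptors and transporters −0.14, ethanol and acetaldehyde metabolism −0.04 and the glucocorticoid response 0.00. Immediate early genes had 0.10, heat shock genes and chaperones −0.04, innate immune signalling −0.01, interferon response and antigen presentation −0.13 (IFI6 0.776-fold), chromatin modifiers 0.07 (TET3 1.27-fold) and cholesterol synthesis and transport 0.01. The RNA quality lists had −0.13 for histone genes and 0.06 for nuclear-retained neuronal RNAs (PCDH9 1.23-fold). Median, mean and test direction differed in sign for pan-neuronal genes, oligodendrocyte precursors, microglia and innate immune signalling.

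**Figure D3:**
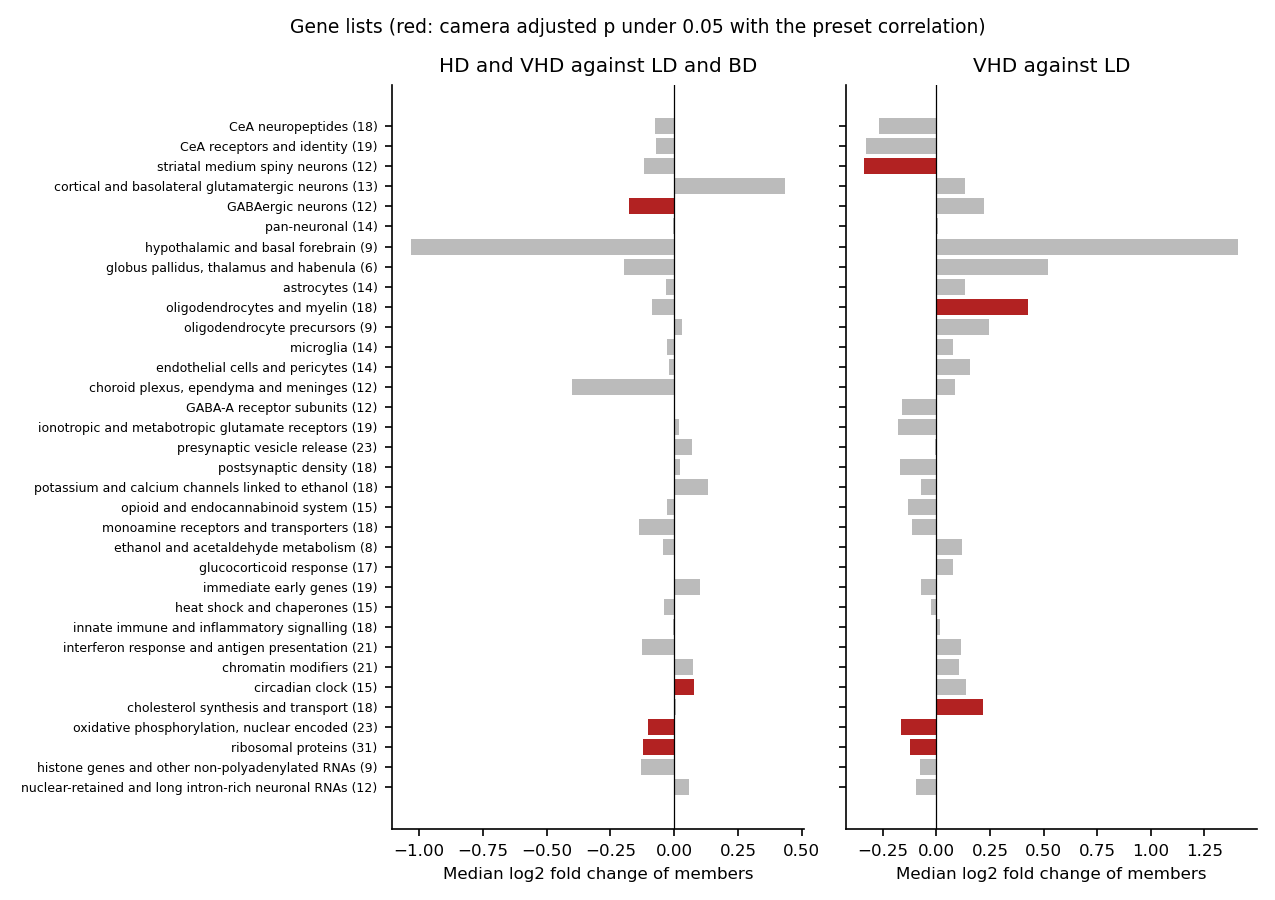
Bars give the median log2 fold change of each list's tested members (number in brackets) between heavy and low drinkers on the left and between VHD and LD on the right, red where camera passed with the preset correlation. Ribosomal proteins lie at −0.12 on both sides, and oligodendrocytes and myelin at −0.09 on the left and 0.43 on the right.

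PENK stood lower in VHD than in LD animals, with a fitted fold of 0.159 (0.0524 to 0.480), and 6 of 6 lay below the LD mean. On the log2 scale of the fit, 5 of 6 lay below it. The groups overlapped, with 1405 to 10512 normalized reads in VHD and 3018 to 32856 in LD. The limma adjusted p of PENK was 0.522 over all genes and 0.0385 adjusted over the list alone for neuropeptides, 0.0321 for the opioid list. CRH was below the LD mean in 6 of 6 VHD animals (fold 0.602, 0.371 to 0.978), while GFAP (1.65) was above it in 6 of 6 and MBP (1.49) in 5 of 6. The other fixed genes had folds of 1.37 for FKBP5, 0.606 for SST, 1.25 for NPY, 1.21 for CRHR1, 1.06 for NR3C1, 0.848 for PDYN and 1.01 for ALDH2. TMEM132D, a membrane protein gene, had the smallest p, at 602 ± 152 normalized reads in VHD (n = 6) against 928 ± 176 in LD (n = 10) and a fold of 0.502 (0.376 to 0.670, adjusted p 0.324 by limma). PSD2 was above the LD mean in 6 of 6, at 2807 ± 340 against 2247 ± 202 normalized reads (1.33, 1.17 to 1.52, adjusted p 0.477). The mitochondrial malic enzyme ME3 was at 1089 ± 217 against 1593 ± 203 normalized reads (0.641), and the ubiquitin ligase component FBXO32 at 1163 ± 223 against 794 ± 135 (1.48). The fold was 1.83 for MARC1, 1.52 for GLT25D2 and 2.16 for OSBPL3, and 0.809 for the kinase PDPK1, 0.564 for HS6ST2 and 0.674 for the actin-binding WDR1.

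By limma 0 genes passed between VHD and LD, with 1116 at an unadjusted p under 0.05 (547 higher, 569 lower) against 651 given by chance. edgeR called 0 (1220 unadjusted) and DESeq2 called 4 (1350 unadjusted), which were AVP, FXYD5, PSD2 and TMEM132D, AVP and FXYD5 being chosen after their values were seen. AVP was at 21751 normalized reads in VHD replicate 5 and at most 69.6 in any other library. For 81.4% of genes the 95% interval of the fold lay within 2-fold. Markers of a neighbouring region stood beside these differences. The acetylcholine-synthesizing enzyme CHAT, of cholinergic neurons, had means of 177 ± 249 normalized reads in LD and 875 ± 771 in VHD, with 3 of 6 VHD animals between 1450 and 1687.

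Of the lists past camera at the preset correlation, the myelin genes stood highest in VHD, with 18 of 18 members above 1-fold and a median log2 fold change of 0.43 (CNP 1.44-fold, CNTN2 1.35-fold). Cholesterol synthesis and transport had 17 of 18 members higher and a median of 0.22 (INSIG1 1.43-fold, HMGCS1 1.41-fold). Oxidative phosphorylation had 22 of 23 members lower (median −0.17, NDUFA4 0.768-fold), ribosomal proteins 29 of 31 lower (median −0.12, RPL30 0.818-fold) and striatal medium spiny neurons 12 of 12 lower (median −0.34, DRD2 0.485-fold). Camera with the preset correlation gave adjusted p-values of 1.23e-06 for myelin, 0.00237 for cholesterol, 0.000357 for oxidative phosphorylation, 0.00125 for ribosomal proteins and 0.0327 for striatal genes. It gave an adjusted p = 0.695 with an estimated correlation for the myelin, cholesterol and oxidative phosphorylation lists and an adjusted p = 0.717 with an estimated correlation for the ribosomal and striatal lists, and fry gave 0.591 to 0.615, so none of the 5 calls held. Hypothalamic and basal forebrain genes had a median of 1.41 with 8 of 9 members higher (camera adjusted p 0.150). In cohort 7a alone, with 2 VHD and 3 LD animals, the medians were 0.14 for myelin, 0.12 for cholesterol, −0.16 for oxidative phosphorylation, −0.08 for ribosomal proteins and −0.14 for striatal genes. No list had a member past the threshold over all genes by limma, and 0 to 6 members lay at an unadjusted p under 0.05. Adjusted over the list alone, PENK passed in both of its lists, RORA in the clock list (1.41-fold, 0.0141), and PCDH9 (1.35-fold, 0.0303), FGF14 (0.673-fold, 0.0490) and RBFOX1 (0.661-fold, 0.0490) among nuclear-retained RNAs. Median, mean and test direction differed in sign for glutamatergic, GABAergic, pan-neuronal, choroid plexus, presynaptic, immediate early and heat shock lists.

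HD animals had little C14orf105, with 56.9 ± 89.4 normalized reads (n = 7) against 210 ± 123 in LD (n = 10) and a fold of 0.0848 (0.0312 to 0.230), 6 of 7 below the LD mean. VHD animals had 254 ± 124 (n = 6) and BD animals 112 ± 142 (n = 5), so VHD did not share the low mean of HD. CD93, a receptor of endothelial and myeloid cells, was below the LD mean in 6 of 7 HD animals (0.595, 0.468 to 0.757), and the cytokine receptor gene IL20RA in 7 of 7 (0.633, 0.484 to 0.827). The unconventional myosin MYO7A was above it in 6 of 7 (1.79, 1.23 to 2.62). The remaining named folds were 1.22 for CDKAL1, 1.35 for GLT25D2, 1.17 for ARFGEF1, 1.21 for ARHGAP21, 0.664 for TCF19 and 0.603 for TMEM176B. Without adjustment for cohort, VHD and LD means were 145 and 152 for CD93, 212 and 181 for IL20RA and 720 and 537 for TMEM176B. They were 60.4 and 55.6 for TCF19, 153 and 151 for MYO7A, 2867 and 2812 for ARFGEF1 and 7518 and 7440 for ARHGAP21. CDKAL1 (285 and 254) and GLT25D2 (373 and 309) were higher in VHD as well. None passed by limma, which called 0 genes with 516 at an unadjusted p under 0.05 (183 higher, 333 lower) and a lowest adjusted p of 0.387, for C14orf105. edgeR called 0 (532 unadjusted) and DESeq2 1 (616 unadjusted), SIRPB1. The 95% interval lay within 2-fold for 88.1% of genes. Without HD replicate 5, which had 246 normalized reads, limma called C14orf105.

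BD animals had more PPDPF than LD animals, with 160 ± 40.2 normalized reads (n = 5) against 101 ± 29.2 (n = 10) and a fold of 1.66 (1.25 to 2.21). They had less DDX60, an interferon-induced helicase, with 46.5 ± 22.5 against 86.2 ± 17.04 normalized reads and a fold of 0.518 (0.364 to 0.736). PRAF2 (1.28), the fatty acid elongation enzyme TECR (1.22), the RNA polymerase II subunit POLR2I (1.32) and LSM12 (1.20) were above the LD mean in 5 of 5 BD animals, as was PPDPF. The mitochondrial leucyl-tRNA synthetase LARS2 (0.792), the DNA repair nuclease ERCC4 (0.799), DPM1 (0.840), the acyl-CoA dehydrogenase ACAD8 (0.719) and DDX60 were below it in 5 of 5. None passed by limma, which called 0 genes with 458 at an unadjusted p under 0.05 (179 higher, 279 lower) and a lowest adjusted p of 0.9999. edgeR called 0 (315 unadjusted) and DESeq2 0 (331 unadjusted). The 95% interval lay within 2-fold for 89.1% of genes.

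With the categories coded in order from LD to VHD, PENK had a fold of 0.582 per category step and did not pass the test. The higher genes with the smallest p were GLT25D2 (1.15 per step), CDKAL1 (1.08), PSD2 (1.08), FBXO32 (1.13) and FHAD1 (1.26). The lower ones were SFXN2, a mitochondrial carrier (0.842 per step), NHLRC1, a ubiquitin ligase of glycogen metabolism (0.889), PLCXD3 (0.865), MGME1, a mitochondrial DNA nuclease (0.895), and ZNF430 (0.903). SFXN2 had means of 165 ± 35.5 normalized reads in LD (n = 10), 118 ± 17.3 in BD (n = 5), 128 ± 31.3 in HD (n = 7) and 110 ± 16.4 in VHD (n = 6). None passed by limma, which called 0 genes with 632 at an unadjusted p under 0.05 (283 higher, 349 lower) and a lowest adjusted p of 0.950. edgeR called 0 (741 unadjusted) and DESeq2 0 (826 unadjusted).

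Between cohorts, which differ in age, DPM1, a subunit of dolichol-phosphate mannose synthase, had means of 468 normalized reads in cohort 4, 409 in cohort 5, 355 in cohort 7a and 449 in cohort 7b. The GABA transporter SLC32A1 had means of 1195, 1774, 1172 and 2084, PCP4L1 of 935, 1402, 1041 and 1484, and DDX26B of 525, 384, 398 and 358. OSBPL3, PAMR1, BCAR1, SYNDIG1L, CLUH and KIAA1731 completed the 10 genes with the smallest p. None passed by limma with category as a term (adjusted p 0.330 for each of the 10). It called 0 genes, with 1225 at an unadjusted p under 0.05, edgeR called 0 (1340) and DESeq2 19 (1660). Without LD replicate 2, limma called 40. Whether the heavy vs low difference itself varied between cohorts 4, 7a and 7b could not be decided. Cohorts 4 and 7b held 1 heavy animal each, so variation between cohorts cannot be told from that between single animals. An interaction term over these cohorts takes in both. It called 0 genes by limma, with 608 at an unadjusted p under 0.05 and a lowest adjusted p of 0.184, for RLBP1, chosen after its values were seen.

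For relative exon use between heavy and low drinkers, limma's F test called 9 of 9817 genes. In ACAD9, a complex I assembly factor, the exon at 148095476 to 148095551 on chromosome 3 had 40 ± 21.4 normalized reads in heavy (n = 13) against 62.3 ± 21.7 in low drinkers (n = 15) (relative log2 −1.43, adjusted p 2.11e-08). In ATP6V1D, a subunit of the proton pump of lysosomes and synaptic vesicles, the exon at 129291574 to 129291735 on chromosome 14 had 123 ± 89.6 against 227 ± 71.3 (relative log2 −1.56, adjusted p 0.00331), and 7 of the 8 animals at or under 54 were heavy. ARHGAP12 (exon at 32099650 to 32099838 on chromosome 10, relative log2 1.81) and FGD4 (exon at 33605179 to 33605237 on chromosome 12, relative log2 1.24) followed, each with an adjusted p of 0.0117. The ARHGAP12 exon was near the floor, at 7.38 ± 6.13 in heavy against 5.27 ± 10.0 in low drinkers. It had 0 to 17 normalized reads in 27 libraries and 40 in BD replicate 1, the shallowest library. The FGD4 exon had 32.2 ± 19.8 against 25.4 ± 15.6. CRYZ, ACSL6, CTNNB1 and H2AFY had an adjusted p of 0.0135 each and were chosen after their values were seen. F tests gave 170 genes at an unadjusted p under 0.05 where chance gives 491, and Simes tests called 103. In 2000 simulated genes, the F test made 15 false calls beside 9, 29 and 60 true calls of 1.5-, 2- and 4-fold exon changes. Simes tests made 56 false calls beside 14, 41 and 64 true ones. Both tests thus made more false calls than the threshold allows. With each exon's own spread in place of 1 spread per gene, 0 genes passed (limma on relative exon values). This test was over 109212 single exons rather than 9817 genes. In the simulated genes it made 23 false calls beside 11, 38 and 60 true ones, so it also made too many. With own spreads, 2804 genes had at least 1 exon at an unadjusted p under 0.05. That number counts single exons of genes with several exons each, so it does not compare with the 170 or the 491. Of 112706 single exons, 0 passed by limma, with 4445 at an unadjusted p under 0.05 against 5635 given by chance.

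The libraries differed widely in the scores of neuron genes and of genes of neighbouring regions. The score of hypothalamic and basal forebrain genes ranged from −2.65 to 4.86 log2 units, that of cortical and basolateral glutamatergic genes from −2.16 to 1.92, that of striatal genes from −0.78 to 2.04 and that of myelin genes from −0.58 to 0.94. CHAT ranged from 0 to 1687 normalized reads and the choline transporter SLC5A7 from 25.5 to 11907, while the cortical transcription factors TBR1 and NEUROD6 ranged from 0 to 694 and from 1.23 to 769. The glutamatergic and the hypothalamic scores ran against each other, with Pearson r = −0.575 over 28 animals (permutation p 0.00138, adjusted 0.00276 over 4 relations) and Spearman rho = −0.626 (permutation p 5e-04). Without the 2 animals farthest from the median, r was −0.645. It was −0.446 in cohort 4, −0.393 in cohort 5 and −0.924 in cohort 7a, and cohort 7b was too small. Of 12 marker scores, 0 differed between heavy and low drinkers by a two-sided permutation test within cohorts (0 at an unadjusted p under 0.05). The lowest permutation p was 0.204, for GABAergic neurons, at −0.18 ± 0.12 (SE), with an adjusted p of 0.875, and the next was 0.205 for choroid plexus genes at −0.32 ± 0.23.

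**Figure D4:**
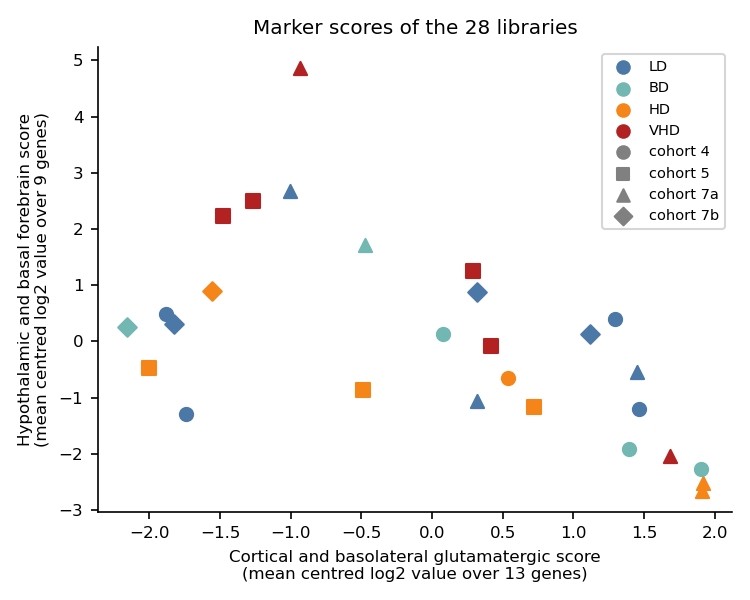
Each point is 1 library, by the score of 13 cortical and basolateral glutamatergic genes and of 9 hypothalamic and basal forebrain genes, both as mean centred log2 values, with colour for the drinking category and shape for the cohort. VHD replicate 5 lies highest at 4.86, and the scores run against each other (r = −0.575).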

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

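Chosen only after the result was seen were the split counts for results with 0 calls, the own-spread test of exons, the test of neighbouring tissue, and the alternatives without the 3 shallowest libraries and with 4 marker scores.

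A single animal lay apart from the rest of its category in 23 of 328 groups of values (7.01%), where chance gives about 1 in 20 groups, or 16.4 of these. HD replicate 1 was highest in HD for ZNF792 at 159 normalized reads, and lowest in HD for THAP4 at 317, BCAR1 at 283 and CLUH at 1079. BD replicate 1 was lowest in BD for RBM10 at 593 and highest for POLR2I at 1251 and LSM12 at 730. LD replicate 1 was lowest in LD for RBM10 at 664, C14orf105 at 20.2 and POLR2I at 467. These are the 3 shallowest libraries. BD replicate 5 was lowest in BD for CRHR1 at 78.8, and highest for NHLRC1 at 201 and for the endothelial score at 0.11. LD replicate 7 was highest in LD for GFAP at 60195. LD replicate 8 had the highest choroid plexus score in LD, at 1.10. HD replicate 5 was lowest in HD for IL20RA at 73.1. Among VHD animals, replicate 5 was highest for PSD2 at 3451, and replicate 6 lowest for IL20RA at 113 and for the GABAergic score at −0.34. VHD replicate 2 was highest for POLR2I at 982 and SFXN2 at 143, replicate 4 highest for MGME1 at 187, and replicate 1 highest for the striatal score at 0.65.

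Of the 9 genes with a call for exon usage between heavy and low drinkers, several had a leading exon whose values fell in 2 separate ranges across the animals, as in ATP6V1D (at or under 54 normalized reads in 8 animals, at least 157 in 20). The 3 shallowest libraries stay open as a source, since 5 of the 9 genes kept the call without them but 4 without HD replicate 1 alone (and 4 without LD replicate 7, a deeper library). A candidate explanation is the single spread per gene that the F test assumes: with each exon's own spread, 0 of the 9 leading exons passed. That test was over 109212 single exons rather than 9817 genes and also made too many false calls in simulated data, so it cannot settle this. Chance is not excluded, since 79 of 100 splits of the animals gave as many genes (9 in the real split, up to 227 in others), and 62 of 100 with animals moved within cohorts (up to 1190). A real difference between drinking groups stays open.

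Ribosomal protein genes (median log2 fold change −0.12) and nuclear oxidative phosphorylation genes (−0.10) lay lower in heavy drinkers. Tissue makeup of the block is argued against only as far as the oligodendrocyte, striatal, cortical and hypothalamic scores follow it. These 4 marker scores as covariates left medians of −0.136 and −0.158. Makeup that these scores do not follow was not tested for either list. Short transcripts could account for both: among random lists matched on exon length and mean value, the medians fell at percentiles 6.83 and 19.8, within the 95% ranges of −0.139 to −0.0763 and −0.121 to −0.0561. Without the 3 shallowest libraries the medians were −0.0790 and −0.0366, which leaves shallow libraries open for the first list and goes with them for the second. Both medians were the same without HD replicate 1 alone, the only heavy animal of cohort 4, so shallow depth and the loss of cohort 4 from the comparison cannot be told apart. Chance is not excluded, since 81 of 100 splits called at least as many lists (4 in the real split, up to 18 in others), or 78 of 100 within cohorts (up to 21), and an effect of drinking stays open.

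Libraries spread from glutamatergic genes such as TBR1 to cholinergic genes such as CHAT, along the first principal component (27.1% of the variance). Unequal shares of neighbouring tissue in the blocks may account for it, but the test could not decide this. The 9 tested hypothalamic and basal forebrain genes, none in another list, had a mean pairwise r of 0.547 over the libraries (0.116 to 0.963), with SLC5A7 up to 11907 normalized reads. CHAT, SLC18A3, SLC5A7, LHX8 and OXT of this list are among the genes that weigh most in the component. Their correlation therefore partly restates the pattern. Depth stays open, since Pearson r of the component with log2 reads was 0.121 (permutation p 0.561) but 0.650 without the 3 shallowest libraries. Over all 28 libraries, Spearman rho was 0.511 (permutation p 0.00635). Within cohorts 4, 5 and 7a, Pearson r was 0.0928, 0.420 and 0.714. The drinking category stays open as well, since heavy minus low was 0.238 SD of the component with an interval of −0.799 to 1.27 (permutation p 0.665).

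For counts past the threshold with a real value of 0, any split gives as many (100 of 100), so the splits say nothing on chance, with a highest other of 1686 for heavy vs low, 1385 for VHD vs LD, 120 for HD vs LD, 3 for BD vs LD, 1768 for the trend, 1990 for cohorts and 2755 for exons. Chance is not excluded for the rest. At an unadjusted p under 0.05, 21 of 100 splits gave as many as the 1116 genes of VHD vs LD (highest other 3631), and 10 of 100 as many as the 1225 of cohorts (highest other 3766). For VHD vs LD lists, 71 of 100 splits gave 5 or more (highest other 21), or 82 of 100 within cohorts (highest other 23). Some splits called over 1000 genes where the real labels called 0, so they separated the libraries more strongly than the real labels did. What these splits follow was not tested.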

How the results depend on the processing

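Chosen only after the result was seen were the alternatives without the 3 shallowest libraries, with 4 marker scores and with an own spread per exon. No paired analysis was possible because the labels pair no animals; replicate numbers only follow the order of the deposited samples. BD vs LD and the trend kept 0 genes under 16 of 16 alternatives each, exons 0 under 5 of 5 and marker scores 0 under 4 of 4. Heavy vs low kept 0 genes under 16 of 17 (1 by DESeq2), HD vs LD under 14 of 16 (1 by DESeq2, 1 with age, C14orf105), VHD vs LD under 14 of 16 (4 by DESeq2, 4 with robust priors and array weights: FXYD5, ME3, PSD2, TMEM132D) and cohorts under 11 of 13 (19 by DESeq2, 2 with 4 scores, GRIN1 and TYMS). Heavy vs low lists went from 4 to 0 with an estimated correlation, 0 by fry and 8 without the 3 libraries. VHD vs LD lists went from 5 to 0 with an estimated correlation, 0 by fry, 13 without a cohort term and 3 with 4 scores. The 4 scores are those of the oligodendrocyte, striatal, cortical and hypothalamic lists, so the loss of the oligodendrocyte and striatal calls of VHD vs LD with them (0.0157 and 0.0986) was fixed beforehand and says nothing on these lists. Exon usage went from 9 genes to 103 by Simes tests, 0 with an own spread, 4 with a pseudocount of 8 (all among the 9), 5 with the filter of 50 (3 of the 9) and 14 without the 3 libraries (5 of the 9). Without a cohort term 8 genes passed, 2 of them among the 9, and without cohort 5, 7 passed (6 of the 9). For 11 settings (pseudocounts, filters, median-ratio rescaling, 4 scores, cohort terms, cohort 5 and the 3 libraries), 541 of 570 values of named genes for heavy vs low and VHD vs LD kept their direction and none passed the threshold. These include the 31 heavy vs low genes without cohort 5, whose folds cannot change, so their direction was fixed beforehand. The log2 fold change of heavy vs low reversed for NPY (0.000234 with median-ratio rescaling, 0.0101 with 4 scores, 0.0508 without the 3 libraries), ALDH2 (0.00385 with median-ratio rescaling, 0.0363 with 4 scores), FKBP5 (−0.00161) and GFAP (−0.0197) without the 3 libraries. Without a cohort term, with age and with a random effect it reversed for CRH (−0.0849, −0.193, −0.0765), SST (0.120, 0.143, 0.0861), CRHR1 (−0.141, −0.188, −0.121), NR3C1 (0.0304, 0.0284, 0.0267) and ALDH2 (0.0694, 0.0530, 0.0636). For VHD vs LD it reversed for CRHR1 (−0.0561, −0.104, −0.0328, and −0.0562 without cohort 5), NR3C1 (−0.0292 with 4 scores) and ALDH2 (−0.0157 with 4 scores, −0.0310 without the 3 libraries). The list median of GABAergic neurons in heavy vs low reversed without a cohort term (0.0635). Leaving out 1 library gave 0 to 0 genes for heavy vs low, BD vs LD and the trend, 0 to 1 for VHD vs LD (1, PSD2, without VHD replicate 6) and HD vs LD (1, C14orf105, without HD replicate 5), 0 to 40 for cohorts (40 without LD replicate 2), 0 to 0 exons and 0 to 0 marker scores. It gave 6 to 16 exon usage genes, with as few as 4 of the 9 kept (without HD replicate 1 or LD replicate 7) (16 without VHD replicate 6 or HD replicate 5, 15 without BD replicate 1, 14 without HD replicate 7). It gave 2 to 13 heavy vs low lists (2 without VHD replicate 6, HD replicate 6 or LD replicate 7, 7 without HD replicate 7, 8 without LD replicate 9, 12 without HD replicate 1, 13 without VHD replicate 5) and 4 to 11 VHD vs LD lists (8 without VHD replicate 1, 2 or 5 or LD replicate 2, 10 without VHD replicate 6, 11 without LD replicate 7). The oxidative phosphorylation call of heavy vs low ended without HD replicate 1 (−0.0366), the only heavy animal of cohort 4. The clock call ended without VHD replicate 6 (0.0418), HD replicate 6 (0.0656) or LD replicate 7 (0.0648), and without a cohort term (0.0477). The GABAergic call (median −0.175) ended without VHD replicates 1 (−0.175), 2 (−0.175) or 6 (−0.116), HD replicates 5 (−0.107) or 6 (−0.131), BD replicates 1 (−0.180), 3 (−0.159) or 4 (−0.0950) or LD replicates 1 (−0.190), 6 (−0.199) or 7 (−0.103), and with a pseudocount of 8 (−0.174), quantile normalization (−0.172), 4 scores (−0.128) or without cohort 5 (−0.175). The striatal call of VHD vs LD (median −0.336) ended without VHD replicates 3 (−0.277) or 4 (−0.283), HD replicates 1 (−0.275), 4 (−0.244) or 5 (−0.319), BD replicate 4 (−0.293) or LD replicates 1 (−0.276) or 8 (−0.222), and with quantile normalization (−0.360) or without the 3 libraries (−0.239). The ribosomal call of VHD vs LD ended without a cohort term (−0.0640) or with 4 scores (−0.0660). Without cohort 5, only the 2 VHD animals of cohort 7a were left for VHD vs LD, and the cholesterol (0.0720), ribosomal (−0.0625) and striatal (−0.239) calls ended. For these changes the cause was not tested, except that fewer animals were compared without HD replicate 1, and without cohort 5 for VHD vs LD. For heavy vs low, leaving out cohort 5 or any of its animals changes the estimate of spread but not the folds. In simulated data with independent genes, limma found 85.1% of 2-fold changes for heavy vs low and 70.1% for VHD vs LD.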

Other observations

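Chosen only after the result was seen were the exons named here and the screen behind them, SIRPB1, and the values of AVP and OXT by library. The screen was a search for exons with a gap in their use across the animals.

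Some exons were nearly absent in part of the animals and abundant in the rest. Whether their genes share a function was not tested. Of 109212 exons screened, 84 in 78 genes had relative values in 2 ranges at least 1.5 log2 units apart, with at least 5 animals in each. Values were relative to the gene's mean, and not all of the 84 were nearly absent in the lower range. An exon of YWHAE had 63 to 109 normalized reads in 16 animals and 618 to 1090 in 12. The exon of UQCRH, a subunit of mitochondrial complex III, at 45647739 to 45647963 on chromosome 1 had 0 to 1 normalized reads in 6 animals and 120 to 305 in the other 22. Another UQCRH exon among the 84, at 45640581 to 45640742, had 569 to 994 in 22 animals and 447 to 839 in 6, so its reads overlapped. The exon of ATP5A1, a subunit of ATP synthase, at 35047187 to 35047335 on chromosome 18 had 2 to 8 in 7 animals and 249 to 404 in 21. The exon of NDUFB2, a subunit of complex I, at 166659483 to 166659561 on chromosome 7 had 0 to 4 in 19 animals and 234 to 441 in 9. An exon of LDHA, lactate dehydrogenase, at 47777177 to 47777350 on chromosome 11 had 0 to 2 in 5 animals and 119 to 642 in 23. An exon of RPL4 at 43172628 to 43172695 on chromosome 14 had 0 to 3 in 22 animals and 70 to 181 in 6. The 12-base exon of ANKS1B, a postsynaptic protein gene, at 97965900 to 97965911 on chromosome 12 had 0 to 11 in 9 animals and 79 to 241 in 19. Inherited variants, reads shared with related gene copies and the alignment were not tested for these exons.

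At the level of whole genes, SIRPB1, an immune receptor of myeloid cells, had 0 to 1.30 normalized reads in 12 animals and 19.3 to 99.5 in the other 16. Its means were 39.3 ± 39.1 in LD (n = 10), 53.5 ± 13.6 in BD (n = 5), 7.25 ± 18.3 in HD (n = 7) and 37.8 ± 40.8 in VHD (n = 6). C14orf105 ranged from 2.03 to 484 normalized reads. The hypothalamic hormones vasopressin (AVP) and oxytocin (OXT) reached 21751 and 4478 normalized reads in VHD replicate 5, against at most 69.6 and 99.7 in the other libraries. The interferon-linked antigen presentation gene CD74 was 1.97-fold (1.23 to 3.15) and the antiviral gene MX1 1.56-fold (1.04 to 2.33) in VHD against LD, neither past the limma test.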
